A study of Mus musculus with 2 samples.

How the data were processed

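Both samples were mouse embryonic hindbrain, pooled over embryos of both sexes at embryonic day 15.5, from which chromatin carrying H3K4me1 was immunoprecipitated and sequenced from fragments of a 300 to 500 bp size range, per the labels. They form 1 group of 2 biological replicates. The labels say that the replicates came from separate pools of 78 and 62 embryos. With a single group no condition was compared with another, and the comparisons were made between the replicates, between parts of the genome and between gene lists.

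The authors deposited 4 peak lists on mm10: one called on each replicate, one called on both replicates pooled, and a list of replicated peaks that, per the deposited record of parent files, was derived from the pooled list and both replicates' lists. Every replicated peak is also in the pooled list with the same coordinates. Its rule of selection is not stated, and 29144 of its 117450 peaks do not share 50% of either peak with a peak of both replicates' lists. The peak caller, the aligner, the thresholds and the read depth are not given in the sources used here. The deposited fold enrichment is a linear ratio of signal over control for each peak, and the deposited -log10 values give its p and q. The lowest -log10 p was 2.02 or above in every list, and 91.0% of replicated peaks had a q of 0.001 or less. The deposited score of the peak format reaches 1000 and was not used. Summit positions are those of the deposited lists. Per the deposited record, the replicate 1 list was made from its alignments and 2 further files, and the replicate 2 list from its alignments and 1 of the same files, so the replicates may share a control. More peaks pass a threshold in a deeper library. As no depth is known, peak numbers are not compared as biology, and intervals cover counting error only. Values per peak were used only to describe, rank or filter peaks within their own list.

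Genes, transcripts and exons came from GENCODE M21 and sequence from GRCm38.p6, the assembly that mm10 names. All peaks on 20 chromosomes lay within the lengths of that assembly. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Coordinates are 1-based. A peak counted as found in another list when at least 50% of its length was covered. Chance overlap came from 100 circular shifts of each chromosome's peaks within the span that holds peaks. Summits were assigned to promoter (within 1000 bp of any annotated TSS), exon, intron or intergenic sequence in that order. Protein-coding genes numbered 21728, without the Y chromosome, with the gene's 5' end as TSS. A promoter was called CpG-rich at an observed over expected CpG ratio of at least 0.6 and a GC content of at least 50% within 500 bp of the TSS.

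For gene lists the share of bases in peaks within 50 kb of each TSS was computed, and a list's median set against 10000 random lists of the same size matched on the number of TSSs in the window in 5 classes, or 1000 for the receptor family, in a two-sided test adjusted by the Benjamini-Hochberg method over 22 lists. Sets were compared by 10000 relabellings of their genes in a two-sided permutation test. A threshold of 0.05 was used. Motifs, matched exactly on both strands, were counted over the whole length of distal replicated peaks, those with a summit over 1000 bp from any TSS. The comparison was sequence of the same length 5 kb to either side that no peak overlapped and that had no TSS within 1000 bp. Each motif was also counted in 10 shuffled versions.

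The gene lists, motifs, tests and most alternatives were chosen before the data were examined. So was the rule for named genes: the 2 members of highest coverage in each neural, regional and housekeeping list and the 1 highest in each non-neural list; the lowest member of the hindbrain, forebrain and Hox lists; and the 10 strongest peaks and 10 longest stretches joined over gaps of up to 3000 bp. Other Hox genes are named to describe the clusters and were chosen after their values were seen. Alternatives were another overlap rule, stricter q thresholds, each replicate's own list, the pooled list, other windows, other random lists and other flanks. Added after seeing the data were replicated peaks covered in both replicates, the TSS of the principal transcript, coverage corrected for GC content, and hindbrain lists without Hox genes.

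The computations were tested on simulated data. Lists of 20000 peaks with 30%, 60% and 90% of peaks planted in both gave those shares back, and all 500 planted X-box sites were found. For lists of 25 genes drawn from 21728, with their measured coverage multiplied by 1.5, 2 and 3, the gene-list test called 16%, 58% and 94% of lists. Random lists had an unadjusted p under 0.05 in 3% of draws. For the comparison of hindbrain with forebrain lists, a planted factor of 3 was called in 58% of draws, a factor of 2 in 24% and no change in 2%. A list that missed the threshold can therefore differ by a factor of 2. Peaks on sequences outside the assembled chromosomes were left out.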

Results

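Histone H3 monomethylated at lysine 4 (H3K4me1), a mark carried by nucleosomes at enhancers and beside promoters, was profiled by chromatin immunoprecipitation and sequencing in the hindbrain of C57BL/6NCrl mouse embryos at embryonic day 15.5. The hindbrain is the most posterior part of the brain and forms the cerebellum, the pons and the medulla. Both samples belonged to 1 group and were pools of tissue from embryos of both sexes. Replicate 1 came from 78 embryos and replicate 2 from 62 embryos. The peak list of each replicate, a list called on both replicates together and the list of replicated peaks were analysed, all on the mouse genome build mm10. Read depth was unknown, because no list states a read count. Replicate 1 had 180419 peaks over 95.1 Mb and replicate 2 had 136232 peaks over 67.2 Mb, so that replicate 1 covered 1.41 times as much sequence. The pooled list held 192101 peaks over 114.5 Mb and the replicated list 117450 peaks over 94.7 Mb. Median peak width was 350 bp in replicate 1, 338 bp in replicate 2 and 588 bp in the replicated list. The median fold enrichment over control, the authors' own value for each peak, was 3.00 in replicate 1, 3.03 in replicate 2 and 3.08 in the replicated list. Values for the replicated list are given below with the mean ± SD over the replicates' own lists (n = 2), most of which lie lower for coverage, as the replicate 2 list covers less sequence.

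The first comparison asked how far the replicates carry the mark at the same places. Of the replicate 2 peaks, 73.7% had at least 50% of their length inside replicate 1 peaks, and 44.8% of replicate 1 peaks had as much inside replicate 2 peaks. The corresponding shares were 3.84% ± 0.14 and 2.67% ± 0.09 (SD, 100 shifts) when the other replicate's peaks were moved along their chromosomes, and no shift gave more than 4.16% and 2.93%. In all, 52.7 Mb lay in peaks of both replicates, which was 78.4% of the bases in replicate 2 peaks and 55.5% of those in replicate 1 peaks. Recovery depended on the strength of the peak. Of the strongest 10% of replicate 1 peaks by fold enrichment 94.8% were found in replicate 2, and of the weakest 10% only 19.8%. For replicate 2 the shares found in replicate 1 were 99.0% in the strongest 10%, 60.5% in the weakest and 57.1% in the class next to it. The replicated list held 61.1% of the pooled peaks. Among its peaks 58.9% had at least 50% of their length covered in both replicates' own lists, and 22791 had no overlap with the replicate 2 list and 7918 none with the replicate 1 list.

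**Figure D1:**
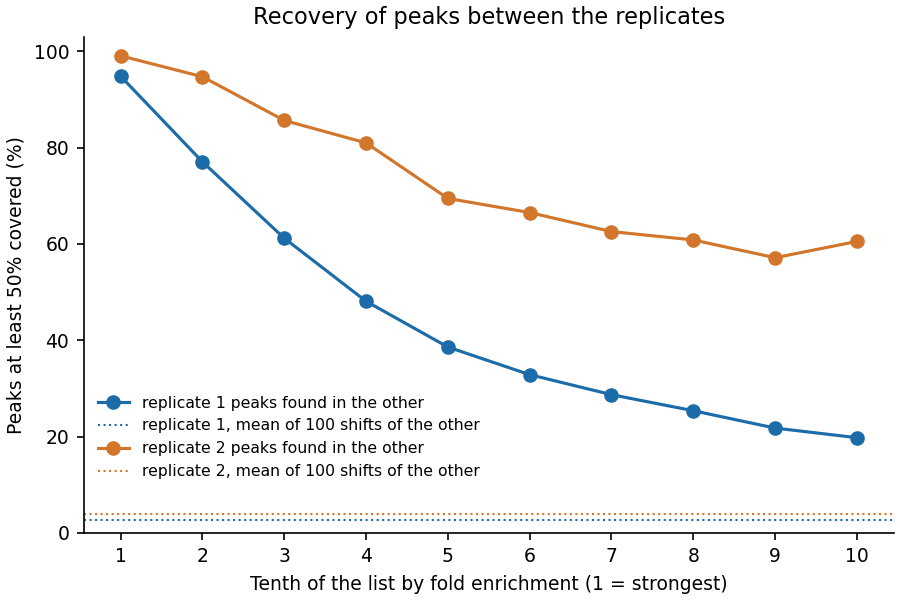
Share of peaks (%) with at least 50% of their length covered by peaks of the other replicate, in 10 classes of equal size ranked on each list's own fold enrichment, with replicate 1 in blue and replicate 2 in orange; dotted lines are the means of 100 shifted lists (2.67% and 3.84%). Recovery falls from 94.8% to 19.8% for replicate 1 and from 99.0% to 60.5% for replicate 2.

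Most replicated peaks lay inside genes and away from promoters. By the position of the summit, 51.8% were intronic, 22.4% intergenic, 21.4% within 1000 bp of an annotated transcription start site (TSS) and 4.37% exonic. In the replicates' own lists the promoter share was 19.6% ± 2.11 and the intronic share 53.6% ± 1.05 (SD, n = 2). Promoters were over-represented 3.41-fold against shifted peaks, of which 6.27% ± 0.17 (SD, 100 shifts) fell at promoters, and no shift gave more than 6.67%. The fold was 5.98 with TSSs of protein-coding genes only and 2.52 within 2500 bp. Intergenic positions held 50.2% ± 0.66 of shifted peaks, so that observed peaks had 0.446 times that share. Strong peaks lay nearer to a TSS than weak ones. The median distance was 1273 bp in the strongest 10%, of which 40.3% lay within 1000 bp of a TSS, and 9750 bp in the weakest, of which 13.4% did. The share depended on the window, at 11.3% within 500 bp and 34.5% within 2500 bp. The peaks had a mean GC content of 49.0% and a mean repeat-masked share of 12.3%, with each peak counted equally. Of all chromosome bases 34.3% were repeat-masked, a share by bases rather than by peaks.

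Around TSSs the mark formed a pair of shoulders with a gap between them at CpG-rich promoters. At the 9726 protein-coding genes with a CpG-rich promoter, 13.9% of bases within 100 bp of the TSS lay in replicated peaks. Coverage rose to 50.9% in the bin from -700 to -600 bp and to 68.7% in the bin from 1100 to 1200 bp downstream. The replicates' own lists gave 11.4% ± 2.52 at the TSS, 42.6% ± 5.83 upstream and 61.9% ± 3.81 downstream (SD, n = 2), so that the gap was larger than the spread between replicates. At the 12002 genes with a CpG-poor promoter coverage was 16.8% at the TSS and reached at most 18.3% in any downstream bin. A peak within 1000 bp of the TSS was present at 92.9% of CpG-rich and 34.3% of CpG-poor genes. Of CpG-rich genes 61.1% had peaks on both sides and none at the TSS itself, against 7.11% of CpG-poor genes. These classes were compared within the same 2 libraries without a test across genes.

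**Figure D2:**
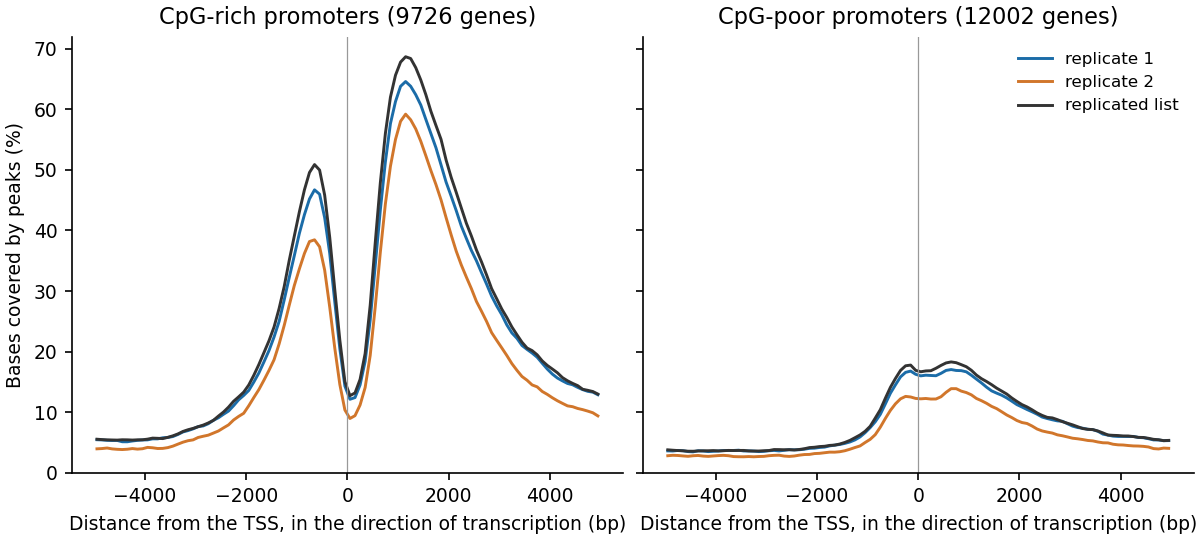
Share of bases in peaks (%) in 100 bp bins from 5 kb upstream to 5 kb downstream of the TSS, for CpG-rich (left, 9726 genes) and CpG-poor promoters (right, 12002 genes), in each replicate's own list and in the replicated list. At CpG-rich promoters coverage of the replicated list dips to 13.9% within 100 bp of the TSS between maxima of 50.9% and 68.7%.

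Genes that pattern the hindbrain and the midbrain-hindbrain boundary had a higher median coverage by replicated peaks than any other fixed list except the anterior Hox genes. Over their 25 members the median share of the 100 kb window around the TSS (50 kb on each side) that lay in replicated peaks was 12.7% (10.4% ± 1.27, SD, n = 2), 3.54 times the median of random lists, and all 25 members lay above that random median of 3.57%. Random lists matched on GC content had a higher median of 7.10%. The ranking among fixed lists was not tested. By number of peaks in the window, with a median of 12, this list was level with pan-neuronal genes and the Sonic hedgehog pathway. Pbx1, a homeodomain partner of Hox proteins (chromosome 1, 168119364 to 168432270), had 24.8% of its window covered (19.7% ± 5.11). Lmx1b, required for the isthmic organiser and for serotonergic neurons (chromosome 2, 33560965 to 33640511), had 21.1% (17.2% ± 3.01), and En1, an engrailed gene of the boundary region and the lowest of the list, had 6.16% (5.05% ± 1.69). All 3 had a peak within 1000 bp of the TSS. None of the 10000 random lists of the same size and local TSS density had as high a median as this list, which gives an adjusted p of 0.0022 in a two-sided resampling test with Benjamini-Hochberg adjustment over 22 lists. Genes are not replicates and neighbours share peaks, so this p and those below describe these libraries.

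Cerebellar lineages also lay above random lists. For the Purkinje and cerebellar GABAergic lineage the median was 8.33% (7.53% ± 1.42) against 3.67% in random lists (adjusted permutation p = 0.011), with 21 of 25 members above the random median. Ebf3, an early B-cell factor family member, led it with 30.4% of its window covered (25.8% ± 5.50). It was followed by Skor1, a corepressor, with 21.8%, and the lowest was Calb1, which encodes the calcium-binding protein calbindin, with 1.01%. For the granule lineage and rhombic lip the median was 7.37% (6.26% ± 1.96) against 3.65% (adjusted permutation p = 0.0253), with 21 of 25 members above. Its highest members were the bHLH genes Neurod2 with 32.4% (27.0% ± 3.10) and Nhlh1 with 22.8% (19.3% ± 1.83), and its lowest was the X-linked gene Zic3 with 0.484%. For brainstem motor, serotonergic and noradrenergic neurons the median was 5.95% (5.14% ± 0.90) against 3.66%, which did not pass the test (adjusted permutation p = 0.109). Its highest members were Fev, the serotonergic ETS factor Pet1, with 13.4% and Lbx1, a homeobox gene of dorsal hindbrain interneurons, with 11.9%. Isl1, a LIM homeobox gene of motor neurons, was the lowest with 1.68%. Against random lists matched on the GC content of the window, the calls for the Purkinje lineage and the granule lineage ended (adjusted permutation p = 0.202 for both). The granule call also ended under 6 of the other 10 alternatives.

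Progenitor, Sonic hedgehog, astroglial and pan-neuronal genes also stood above random lists. For neural progenitors the median was 10.3% (8.91% ± 2.20) against 3.52% (adjusted permutation p = 0.0022). Notch1, the receptor that keeps progenitors undifferentiated, had 39.4% of its window covered (33.3% ± 6.29) and Nes, which encodes nestin, had 30.8% (26.8% ± 2.18). The Sonic hedgehog pathway, which drives granule cell progenitors to divide, had a median of 9.59% (8.51% ± 1.39) against 3.50% (adjusted permutation p = 0.0141). All 16 of its genes had a peak within 1000 bp of the TSS, among them the coreceptor gene Boc with 23.4% of its window covered and the receptor gene Ptch1 with 22.1%. Astroglial genes had a median of 9.38% (7.31% ± 2.42) against 4.54% (adjusted permutation p = 0.0343), led by the nuclear factor I gene Nfix with 41.4% (34.6% ± 8.60), the highest coverage of any gene in the fixed lists, and by Id3 with 17.9%. Pan-neuronal genes had a median of 8.37% (7.13% ± 1.26) against 4.03% (adjusted permutation p = 0.0226), led by Rbfox3, which encodes NeuN, with 29.4% and the adhesion molecule gene Ncam1 with 21.5%. Their call ended against random lists not matched on TSS density (adjusted permutation p = 0.101). The oligodendrocyte lineage, with a median of 7.82% (adjusted permutation p = 0.11), and the choroid plexus and roof plate, with 5.87% (adjusted permutation p = 0.252), did not pass. Their highest members were Sox8 with 18.4%, Cnp with 16.5%, Foxj1 with 13.1% and Msx2 (9.31% ± 0.78 over the replicates' own lists). With GC-matched random lists the calls for astroglia (adjusted permutation p = 0.202) and the Sonic hedgehog pathway (adjusted permutation p = 0.154) ended. The astroglial call also ended under 5 of the other 10 alternatives.

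**Figure D3:**
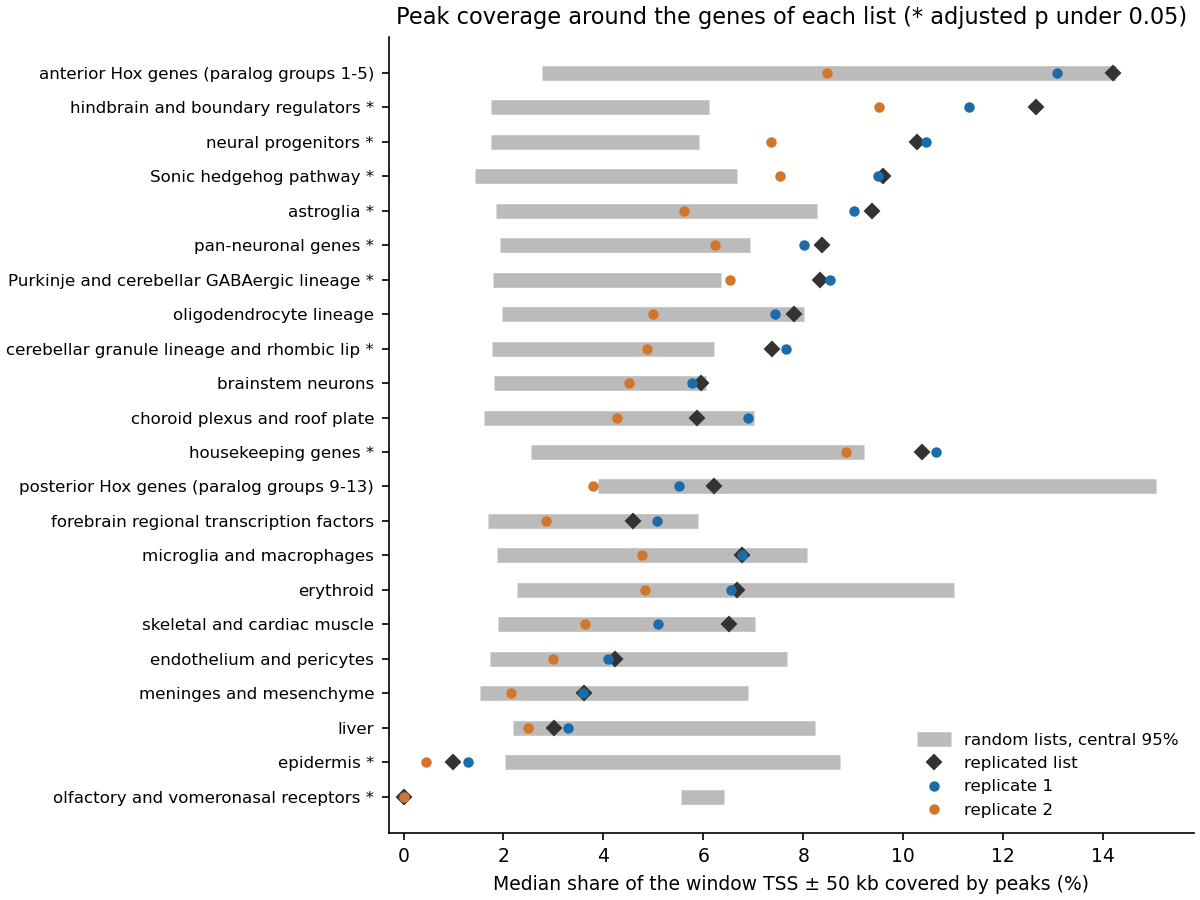
Median share (%) of the window from 50 kb upstream to 50 kb downstream of the TSS that lay in peaks, for each gene list, in the replicated list (diamonds) and in each replicate's own list (circles); grey bars span the central 95% of medians of random lists, for the replicated list. Asterisks mark lists with an adjusted p under 0.05, from hindbrain and boundary regulators with 12.7% to olfactory and vomeronasal receptors with 0%.

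Lists of marker genes of other cell types that dissected tissue can hold mostly did not stand apart from random lists. Medians were 6.77% for microglia and macrophages (4.59% in random lists), 6.67% for the erythroid list (6.30%) and 6.51% for muscle (4.17%). They were 4.23% for endothelium and pericytes (4.14%), 3.62% for meninges and mesenchyme (3.74%) and 3.02% for liver (4.91%). The adjusted permutation p ran from 0.162 to 0.947, which does not show that these lists equal random ones. Their highest members were Cd68 with 19.8%, Nfe2 with 27.9%, Des with 19.1%, Egfl7 with 14.3%, Prrx2 with 16.3% and Apoa2 with 17.1%. Of these 6 genes Des alone had a replicated peak within 1000 bp of its TSS. Epidermal genes fell below random lists with a median of 0.987% (0.87% ± 0.60) against 5.02% (adjusted permutation p = 0.0226), and their highest member was Grhl3 with 13.3%. In windows of 20 kb this call ended. Of 1462 olfactory and vomeronasal receptor genes, which are silent outside sensory neurons, 1280 had no replicated peak in the window and 1 had a peak within 1000 bp of the TSS (median 0%, adjusted permutation p = 0.011). With GC-matched random lists, whose median was also 0%, the test could not place the receptors below, as no median can lie under 0%. Whether GC content accounts for their low coverage was therefore not decided. Housekeeping genes stood above random lists with a median of 10.4% (9.75% ± 1.27) against 5.56% (adjusted permutation p = 0.0342), led by Eef2 with 23.9% and Vcp with 19.3%. Their call ended with GC-matched lists (adjusted permutation p = 0.0836), in windows of 100 kb (0.0836) and by number of peaks (0.0952).

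Taken as sets, the neural lists exceeded the non-neural lists. Median coverage was 8.48% over 239 neural genes and 3.81% over 141 non-neural genes, a difference of 4.67 percentage points that no relabelling of the genes reached (p = 0.0001, the smallest that 10000 relabellings can give, two-sided permutation test). The difference was 3.07 percentage points in replicate 2's own list, 5.08 in replicate 1's and 3.00 with coverage corrected for GC content, an alternative chosen after seeing the data. The sets also differed in promoter class, which was not matched. CpG-rich promoters ranged from 5 of 20 genes (astroglia) to 19 of 24 (neural progenitors) across neural lists. They ranged from 1 of 22 (liver) to 7 of 18 (meninges and mesenchyme) across non-neural lists. The housekeeping list, with 19 of 25, was in neither set and had a median of 10.4%. The difference therefore cannot be read as neural alone.

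Hindbrain genes were also compared with regulators of another brain region, the forebrain, since region is what the labels name. The 116 genes of the 5 hindbrain lists had a median of 8.28% and the 25 forebrain transcription factor genes one of 4.60% (3.96% ± 1.58, SD, n = 2). The difference of 3.68 percentage points passed a two-sided permutation test with 10000 relabellings (p = 0.0107), and was 2.95 in replicate 2's own list (p = 0.0071) and 3.59 in replicate 1's (p = 0.0046). With coverage corrected for the GC content of the window it was 2.05 (permutation p = 0.0323, chosen after seeing the data). Among forebrain genes the highest were Gsx2, a homeobox gene of the lateral ganglionic eminence, with 8.74% (7.07% ± 1.55) and Lhx6, of migrating cortical interneurons, with 8.39% (7.29% ± 1.48), and the lowest was Lhx8 with 1.33%. All 3 had a peak within 1000 bp of the TSS, as did 21 of the 25 forebrain genes. The forebrain list itself did not stand apart from random lists (adjusted permutation p = 0.42). Taken singly, the anterior Hox, boundary, granule and Purkinje lists each exceeded the forebrain list (adjusted permutation p from 0.0003 to 0.00489 over 9 lists) and brainstem neurons did not (difference 1.35 percentage points, adjusted permutation p = 0.197). The relabelling did not match TSS density. Random lists matched on it had a median of 8.72% for the anterior Hox list and 3.57% for the forebrain list. For the boundary, granule and Purkinje lists it was 3.57% to 3.67%. Windows of Hox genes also overlap within a cluster, so the p of the anterior Hox list overstates its distance from the forebrain list. Neural progenitors, astroglia, the oligodendrocyte lineage and pan-neuronal genes, lists of no single region, exceeded the forebrain list as well (adjusted permutation p from 0.0003 to 0.00787), so the difference is not specific to hindbrain regulators.

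Anterior Hox genes, which are expressed in the hindbrain, carried more of the mark than posterior Hox genes, which are expressed behind it, but the difference did not pass the test. In windows of 5 kb on each side of the TSS the median was 13.5% over 15 genes of paralog groups 1 to 5 and 2.09% over 16 genes of groups 9 to 13, a difference of 11.4 percentage points (p = 0.0688, two-sided permutation test). It passed in each replicate's own list (permutation p = 0.0074 and 0.0076) and in the pooled list (p = 0.0022). The Hoxa cluster showed it most fully, with 15.8% to 29.8% at Hoxa1 to Hoxa5, and 0% at Hoxa9, Hoxa10 and Hoxa11. At Hoxa13 coverage was 14.7%. In the Hoxb cluster Hoxb2 had the highest coverage of all (35.7% ± 8.70 over the replicates' own lists) and Hoxb1 had 13.5%, whereas Hoxb3 and Hoxb4 had 0% and the posterior genes Hoxb9 and Hoxb13 had 13.4% and 4.45%. The anterior median was therefore below the posterior one in the Hoxb cluster (3.27% against 8.91%) and level with it in the Hoxd cluster (11.4% against 11.6%). No replicated peak lay in the windows of the 5 posterior Hoxc genes. The posterior Hoxd genes ranged from 4.18% to 14.8%, and Hoxd1, Hoxd3 and Hoxd4 from 11.4% to 17.8%. Values of single genes can describe a neighbour, because some annotated 5' ends lie in another gene's locus. The TSS of the principal transcript differs for 8 of the 15 anterior and 4 of the 16 posterior genes. The 5' end of Hoxa3 (chromosome 6, 52213336) lies beyond that of Hoxa5 (52204587), towards Hoxa9 (52231089). The 5' ends of Hoxd3 and Hoxd4 are 2 bp apart and give the same value, and that of Hoxc5 (chromosome 15, 102967443) lies beside that of the posterior gene Hoxc10 (102966796). In 50 kb windows, which overlap within a cluster, the highest anterior members were Hoxa2 (12.8% ± 4.47 over the replicates' own lists) and Hoxb4 (11.7% ± 3.68), and the lowest was Hoxc5, measured at that position, with 3.56%. The highest posterior members were Hoxd9 (10.3% ± 1.23) and Hoxd10 (9.46% ± 1.13), and Hoxc13 was the lowest with 0%. The median of neither list stood apart from random lists there (adjusted permutation p = 0.106 and 0.256), although the anterior list did in the pooled list (adjusted permutation p = 0.0381), by number of peaks and against unmatched lists.

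Distal peaks, those with their summit over 1000 bp from any TSS, were searched for motifs of transcription factors. Wide peaks among them can reach nearer to a TSS, whereas the flanks had no TSS within 1000 bp. The X-box, the palindromic site of regulatory factor X (RFX) proteins, had the highest ratio of the 18 motifs. It occurred 612 times in 91664 distal peaks and 55 times in 119743 flanking regions, a ratio per kb of 12.6 (95% exact counting interval 9.56 to 16.9), and the ratio exceeded 1 on 19 of 19 autosomes. The ratio was 11.5 ± 0.72 over the replicates' own lists (SD, n = 2) and 12.2 (8.68 to 17.5) within 200 bp of summits. The highest of 10 shuffled versions of the motif reached 1.75. The full nuclear factor I site had a ratio of 3.00 (2.22 to 4.11), from 159 and 60 matches, above 7 of 10 shuffled versions. It depended on the regions compared, at 4.85 (3.40 to 7.07) with flanks 10 kb away and 4.05 (2.78 to 6.02) within 200 bp of summits. The E-box CAGCTG, bound by proneural bHLH factors, had 1.70 ± 0.07 (SD over 19 autosomes), above 9 of 10. Ratios near 1 that nevertheless exceeded all 10 shuffled versions were found for the POU octamer ATGCAAAT (1.10 ± 0.11, shuffled at most 0.819), the MEF2 site (1.15 ± 0.19, at most 0.831) and the site of LIM and paired-class homeodomains (1.02 ± 0.11, at most 0.888). Peaks were richer in GC than flanks (48.8% against 44.3%). Ratios of 1.81 for EBF, 1.61 for CTCF, 1.39 for MEIS and 1.29 for a shortened REST site were within the range of their shuffled versions, and that of CTCF was 3.36 (2.93 to 3.85) within 200 bp of summits. GATA, HNF4 and SOX matches were rarer in peaks than in flanks, with ratios of 0.856, 0.858 and 0.914, again within the range of shuffled versions. Within 200 bp of summits the SOX ratio was 0.986 (0.924 to 1.05), while those of GATA and HNF4 were 0.803 and 0.813. Of the others, AP-1 (0.999), PU.1-type ETS (1.01), the E-boxes CAGATG and CATATG counted together (1.02), the shortened p53 site (1.03) and HNF1 (0.932) lay near 1.

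**Figure D4:**
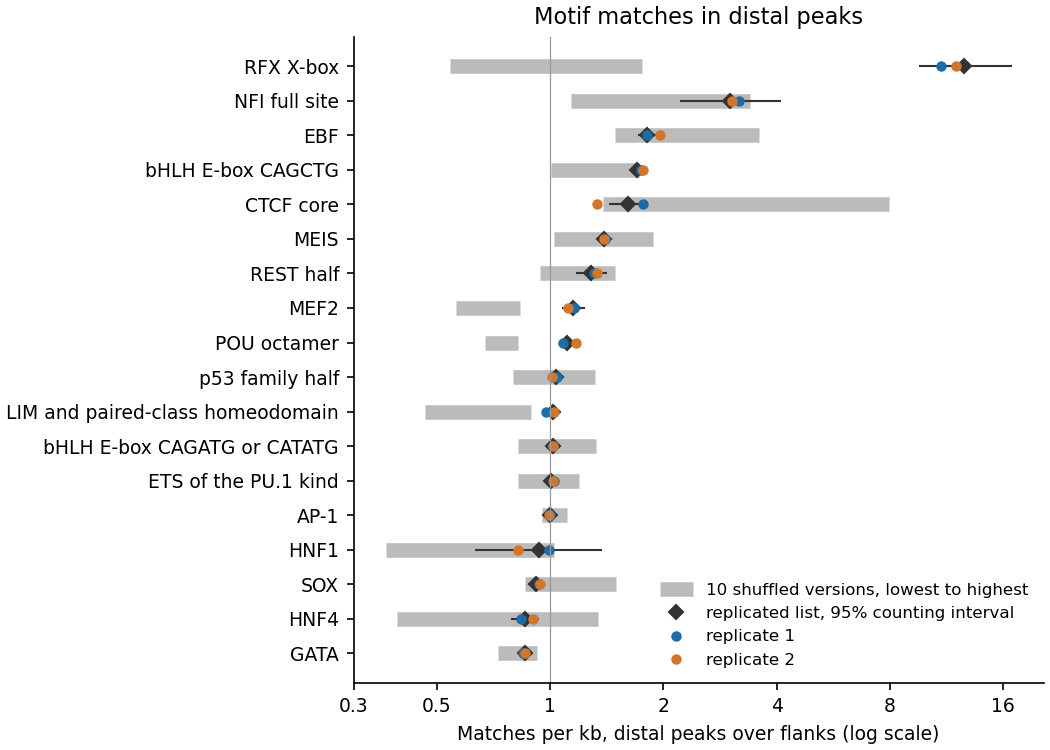
Matches per kb in distal peaks over those in flanking sequence 5 kb away (log scale) for 18 motifs, in the replicated list (diamonds, with 95% counting intervals) and each replicate's own list (circles); grey bars span 10 shuffled versions of each motif. The RFX X-box lies at 12.6, beyond its shuffled versions, which reach 1.75.

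Peaks were spread unevenly over chromosomes, and the X chromosome held few. Replicated peaks had a density of 47.3 per Mb over the 19 autosomes, from 35.1 on chromosome 3 to 72.4 on the gene-dense chromosome 11. On the X chromosome 911 peaks gave 5.33 per Mb, a ratio to autosomes of 0.113. The ratio was 0.116 in replicate 1 and 0.105 in replicate 2. No list had a peak on the Y chromosome. The median fold enrichment of the X-linked peaks, 2.97, was close to the 3.08 of autosomal peaks, but these medians cover called peaks only. In the strongest 10% of replicated peaks the density ratio of X to autosomes was 0.0172, against 0.0727 to 0.172 in the weaker classes of 10%.

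**Figure D5:**
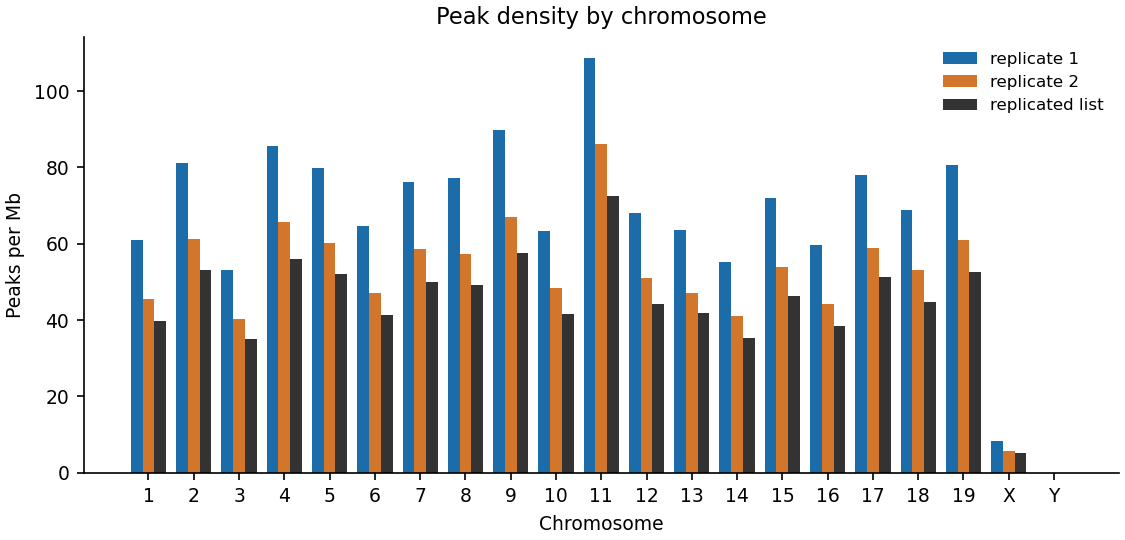
Peaks per Mb on each chromosome in each replicate's own list (blue and orange) and in the replicated list (black). The X chromosome has 5.33 replicated peaks per Mb against 47.3 on autosomes, and the Y chromosome has none.

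The strongest replicated peaks mostly lay beside promoters, and 8 of the first 10 had their summit 1079 to 3480 bp from a TSS. The highest fold enrichment, 11.5, was at chromosome 15, 75910487 to 75913705, over Tigd5 with its summit 1683 bp from the TSS. It was followed by peaks inside Stk11, the kinase gene LKB1 (chromosome 10, 80116574 to 80119741, fold 11.1), and inside Mknk2 (chromosome 10, 80670949 to 80675593, fold 11.0). A peak of 7761 bp in Ncor2, a nuclear receptor corepressor gene, had a fold of 10.7 with its summit 38137 bp from the TSS, and a peak 44585 bp from the TSS of Sirt1 overlapped that gene's annotated span with a fold of 10.6. The summits of the remaining 5, beside Srp68, Srsf6, Kctd5, Rubcn and Ctsd with folds of 10.3 to 10.5, lay 1079 to 1428 bp from a TSS. The mark also formed long domains. Joined over gaps of up to 3000 bp, the replicated peaks made 57059 stretches, of which 319 were at least 20000 bp long and 20 at least 50000 bp. The longest covered 156268 bp of chromosome 11 (88453325 to 88609592) in Msi2, which encodes the RNA-binding protein musashi 2 of neural progenitors, and 72.4% of it lay in peaks (67.9% in replicate 1, 56.5% in replicate 2). The next, of 99045 bp, lay in Ssbp3. Gse1 held a stretch of 89017 bp and another of 83831 bp, and Map4k4, Ccdc85c, Zmiz1, the ephrin receptor gene Ephb2, Ncor2 and Med13l held those from 84065 down to 63603 bp.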

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

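A few peaks lay on sequences outside the assembled chromosomes, which no comparison used; a list with more than 3, the limit that a count of 0 allows, is given here. The replicated list held 4 such peaks, the pooled list 6 and the replicate 2 list 4. With 2 samples in 1 group, neither outlying samples nor differences between groups were testable.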

How the results depend on the processing

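Overlap of the replicates stayed above every shifted list for all 5 alternatives (34.8% to 57.5% of replicate 1 peaks, 46.0% to 81.6% of replicate 2 peaks), and so did the promoter share for 8 (11.3% to 34.5%). The number of lists above random lists, 8 as reported, was 5 in windows of 100 kb on each side, 4 with random lists not matched on TSS density and 3 with random lists matched on GC content. It was 6 to 8 with a single replicate's list. In replicate 2's own list, in windows of 100 kb and with peaks at least 50% covered in both replicates the granule and astroglial calls ended, the astroglial call also in windows of 20 kb, the granule call also at a q of 0.001 or less, and the granule and housekeeping calls by number of peaks. The housekeeping call ended in windows of 100 kb too. Random lists not matched on TSS density ended the granule, Purkinje, pan-neuronal, astroglial and Sonic hedgehog calls. The anterior Hox list lay above random lists in the pooled list, by number of peaks and against unmatched lists, and below their median, without a call, with peaks covered in both replicates. Brainstem neurons fell below the random median with GC matching (5.95% against 6.50%). Hindbrain and boundary regulators and neural progenitors stayed above random lists in all 11 alternatives. Epidermis stayed below in 10, and its call ended in windows of 20 kb. The hindbrain against forebrain difference passed in all 11 alternatives (2.05 to 4.77, the upper end in the pooled list), and neural against non-neural in 10 (2.86 to 8.26). Anterior against posterior Hox genes, which missed the threshold as reported, passed with a single replicate's list (differences of 9.28 to 10.7 percentage points), with the pooled list (12.9), in windows of 10 kb (7.15) and at the TSS of the principal transcript (11.5, an alternative chosen after seeing the data), and missed it in 3 others. The cause was not tested. Motifs higher in peaks than in flanks on at least 15 of 19 autosomes numbered 8, and 7 to 10 under the alternatives.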

Other observations

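Gene families named by symbol were not among the fixed lists, and 22 of them were chosen after seeing the data but before their own values. Single members, among them Ephb2, Notch1 and Sox8, already appeared in the results above, so the choice was not blind to them. Guidance molecules of growing axons stood out: semaphorins and plexins had a median coverage of 14.9% (12.8% ± 2.52, SD, n = 2) over 29 genes, and ephrins and Eph receptors 14.3% (12.3% ± 2.00) over 22 genes. Both stayed above random lists matched on GC content (adjusted permutation p = 0.000629 and 0.00684 over 22 families, two-sided resampling test). Sema3f had 33.8% of its window covered and Ephb2 37.7%. Against lists matched on TSS density, Notch ligands, receptors and Hes factors (14.2%), Wnt ligands and Frizzled receptors (9.37%), ribosomal proteins (9.53%), ionotropic glutamate receptors (9.09%), SOX factors (8.21%) and potassium channels (5.49%) also lay above, but none of these 6 did with GC matching. Replication-dependent histone genes (10.8%) and genes named Zfp (4.77%) lay above in the GC-matched lists alone.

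Other families had low medians. Medians were 0% for 64 defensin and 61 serpin genes, 0.209% for 100 cytochrome P450 genes, 0.882% for 33 claudin genes and 1.99% for 55 interferon and interleukin genes, all below both kinds of random list. Protocadherins had a median of 0.229% over 68 genes (adjusted permutation p = 0.000629 in both), although Pcdhgc3 and Pcdhgc4 at the end of the gamma cluster had 39.5% each, in windows that overlap. Where members lie side by side, as these and the histone genes Hist1h2bh and Hist1h3f do, windows overlap, whereas random lists draw genes one by one. The p of such a family then overstates how far it stands apart. GABA-A receptor genes had 0.977% and were below the TSS-matched lists only (adjusted permutation p = 0.022, and 0.712 with GC matching). Collagens (3.12%, adjusted permutation p = 0.0148) and cilium genes (4.70%, adjusted permutation p = 0.0411) lay below the GC-matched lists only. Forkhead factors, proteasome subunits and Bmp and Tgf-beta ligands stood apart in neither.

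The scarcity of peaks on the X chromosome was weighed against 3 technical explanations, with tests set before their results were seen, except the scaling by a factor, which was added afterwards. Fewer CpG-rich promoters are not the whole cause, since X-linked genes with such a promoter had a peak within 1000 bp in 47.4% of 228 cases and autosomal genes in 94.0% of 9498, a ratio of 0.504 (95% interval 0.439 to 0.578). Sequence composition and gene content account for part of the gap, because autosomal tiles of 100 kb matched on GC content, repeats and TSSs held 1.97 ± 0.08 peaks (SD, 100 draws) against 4.89 in all autosomal tiles, but X tiles held 0.576, a ratio of 0.292 that no draw raised above 0.329. Fewer X copies could still contribute. The density ratio of X to autosomes was 0.0172 in the strongest 10% of peaks, which had been set to exclude this. Yet a lower copy number may also lower the fold enrichment, depending on a control that is not known. It would then empty that class itself. Autosomal folds were also multiplied by a factor, with floors at the lowest 1%, 5% or 10% of folds. At 0.75, the factor for equal numbers of both sexes, the ratio of X to matched tiles was 0.346, 0.464 or 0.543. At that factor a gap was left under each floor. The rule by which peaks were called is not known, however, and need not be a floor on fold. The scaling therefore cannot show that copy number leaves a gap. At 0.5, the factor for copies in male embryos alone, the ratio was 1.07, 1.84 or 2.34, so that no deficit was left. The pools hold both sexes, so this factor does not describe their copy number. The sex ratio is not known, so how much copy number contributes stays open. No biological explanation, such as fewer active copies, was tested, and the scaling cannot tell fewer active copies from fewer copies.

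The concentration of RFX X-boxes in distal peaks was weighed next; the comparison with shuffled versions was set after the result was seen and the other 2 before. Base composition does not account for it, since the ratio was 7.21 times that of the highest shuffled version. Nor does a repeat family, since the ratio on sequence that is not repeat-masked was 12.7 (95% interval 9.07 to 18.2). Because RFX proteins control genes of cilia, X-box peaks may lie nearest to these more often. Of 608 such peaks 3 did (0.493%), against 286 of the other distal peaks (0.314%). The odds ratio was 1.57 (95% interval 0.322 to 4.67, Fisher's exact test p = 0.446), which leaves the question open. Peaks with their summit within 1000 bp of a TSS were left out, so a link through those promoter peaks could not show. The X-box peaks lay a median of 51954.5 bp from the nearest protein-coding TSS, against 45573.5 bp for the other distal peaks. The X-box peaks were also wider (median 1148.5 against 557 bp) and stronger (median fold 3.74 against 3.00), and a wider peak has more sequence in which to hold a match. That these peaks mark RFX-bound enhancers of hindbrain cells is a hypothesis that these lists alone do not test.

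GC content was weighed as a cause of the high coverage of neural lists with random lists matched on it, an alternative planned beforehand, but its use as a test of the cause and the correction for GC content were chosen after the result was seen. Coverage rose steeply with it, from a median of 0% in the 10% of genes with the lowest window GC to 16.2% in the 10% with the highest. It is not the whole cause for hindbrain and boundary regulators or pan-neuronal genes, each with an adjusted permutation p of 0.0088 against GC-matched lists. For the regulators, however, the median of random lists rose from 3.57% to 7.10%. Neural progenitors passed the threshold of 0.05 narrowly (adjusted permutation p = 0.0462). They missed a stricter limit that the regulators and pan-neuronal genes passed. This limit was also chosen after the result was seen. For neural progenitors the part of GC content therefore stays open. For the Purkinje lineage, granule lineage, astroglia and Sonic hedgehog pathway it stays open, since none passed (lowest adjusted permutation p = 0.154). The power of the GC-matched test was not simulated. Lists that are 1.5 or 2 times random ones matched on TSS density are called in 16% or 58% of simulations. The difference between hindbrain and forebrain lists remained with coverage corrected for GC content (2.05 percentage points, p = 0.0323, permutation test).

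Among X-linked genes the highest coverage was at Bcor with 18.4% (12.1% ± 1.88), a corepressor gene, while 50.5% of 948 X-linked genes had no replicated peak in the window, against 16.7% of autosomal genes. The 11 list genes on the X chromosome had from 0%, at Plp1 and Gata1, to 5.96%, at Dcx. X-box matches per Mb of distal peak were 11.4 in the strongest 10% and 7.80 in the weakest, with a minimum of 4.66 between them. Strong peaks seen in a single replicate were few: of the strongest 10% of replicate 1 peaks 178 had no base in common with replicate 2 peaks, and 41 the other way round.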
